A study of Mus musculus with 2 samples.

How the data were processed

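H3K9ac was profiled by chromatin immunoprecipitation followed by sequencing in neural tubes of mouse embryos (strain B6NCrl) at embryonic day 11.5, in 2 biological replicates made from pools of 109 and 88 embryos. Per the labels, chromatin fragments were 300 to 500 bp long. The deposited files are 4 peak lists in narrowPeak format on the mouse assembly mm10. Per the descriptions deposited with the samples, 1 list was called on replicate 1, 1 on replicate 2 and 1 on the alignments of both replicates together (the pooled list), and the replicated list was derived from these 3 lists. The peak caller and its version, the rule by which a peak counted as replicated and the read depth are not given in the sources used here. Each of the 31704 replicated peaks had the same bounds as a pooled peak. Of them, 92.7% overlapped a peak of each replicate by at least 50% of either peak, and 0 of the 5690 other pooled peaks did.

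The signal value of each peak is the authors' deposited value, and what it is relative to is not given in the sources used here. The deposited p-value and q-value of each peak are given as −log10, per the narrowPeak format named in the file descriptions. Signals were ranked or described only within a list. All replicate peaks had a deposited −log10 p of at least 2.00. Peaks outside the 21 assembled chromosomes (5 of 31709 in the replicated list) were left out of the comparisons.

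Positions of genes, transcription start sites (TSS) and exons came from GENCODE release M21 (Ensembl 96) on GRCm38, the assembly that mm10 names, and CpG dinucleotides within 500 bp of each gene's 5′ end were counted in the GRCm38 sequence. Every peak ended before the end of its chromosome in that sequence. All 343 genes of the lists written out by symbol were found in the annotation. Coordinates are given 1-based on mm10.

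A gene was called marked where a peak lay within 1 kb of any of its annotated TSS. Overlap between replicates meant at least 1 bp, and its chance level came from 100 circular shifts of the other list along each chromosome. Shares have 95% Clopper-Pearson intervals, which cover counting error only. The 25 gene lists were fixed before the data were examined and were compared with the other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 25 lists. Genes are not replicates of the experiment, so this test says whether a list stands apart from other genes in these libraries. Breadth was the length covered by replicated peaks within 5 kb of the gene's 5′ end. The median over a list's marked genes was compared with 100000 random sets of marked genes by a two-sided permutation test, whose smallest p is 2.0e-05, in lists with at least 3 marked genes. Fisher's test and the permutation test treat genes as independent, so p can be too small for lists of neighbouring genes, such as the Hox genes. The replicates were compared by the exact McNemar test on the 57218 strongest peaks of each. The genes named were fixed by rule, namely the 3 members of each list with the highest promoter signal and up to 3 without a promoter peak, the 15 genes with the greatest covered length, the 10 with the highest promoter signal, and the 5 with the strongest promoter peak in 1 replicate and none in the other, while any member of a fixed list could be named.

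Alternatives covered other TSS distances, the 5′ end alone, the pooled list, each replicate list alone, q of at most 1e-05, a background without receptor genes, stratification by promoter CpG count in 5 classes, other windows for breadth and other overlap rules. The combination of CpG stratification with q of at most 1e-05 was chosen after seeing the data. The tests were tried on simulated data with known answers. Among 21938 simulated genes, a list of 20 with 90% marked against 64% of other genes was called in 59 of 100 draws at an unadjusted p of 0.05, a list with 30% marked in 87 of 100, and a list with 64% marked in 3 of 100, so that short lists can miss a difference of this size. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.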

Results

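The series measured acetylation of lysine 9 of histone H3 (H3K9ac), a histone modification found at active promoters and enhancers, by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos at embryonic day 11.5. The neural tube is the embryonic precursor of the brain and spinal cord. There was 1 group with 2 biological replicates. Replicate 1 was prepared from a pool of 109 embryos and replicate 2 from a pool of 88 embryos, both of mixed sex. Each replicate had its own peak list, and 2 further lists covered both replicates, a pooled list and a list of replicated peaks. On the assembled chromosomes replicate 1 had 57218 peaks covering 31.9 Mb and replicate 2 had 68802 peaks covering 35.3 Mb, a mean of 33.6 ± 2.42 Mb (SD, n = 2). The pooled list held 37394 peaks over 27.8 Mb, and the replicated list held 31704 peaks over 26.4 Mb, which is 0.970% of the assembled chromosomes. The pooled list held fewer peaks than either replicate list and may have been called or filtered differently, which bears on every contrast between a replicate list and the replicated list. Sequencing depth is unknown because the peak lists carry no read counts. The design has no second tissue or condition, so the comparisons are between the replicates, between regions of the genome, and between gene lists fixed before the data were examined. The signal of a peak is the authors' own value and was used only to rank or describe peaks within a list.

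The first comparison asked how far both pools of embryos gave the same regions. Of the replicate 1 peaks, 58.4% (33441 of 57218, 95% Clopper-Pearson interval 58.0% to 58.8%) overlapped a replicate 2 peak by at least 1 bp, whereas circular shifts of the other list gave a mean of 2.86% and a maximum of 3.55% over 100 shifts. Of the replicate 2 peaks, 48.0% (33044 of 68802, interval 47.7% to 48.4%) overlapped a replicate 1 peak, against a mean of 2.38% for shifted lists. The strongest 10% of each list was shared in full, 5721 of 5721 peaks of replicate 1 and 6880 of 6880 peaks of replicate 2. In the weakest 10% the shared fraction was 26.9% for replicate 1 and 21.5% for replicate 2. Peaks of replicate 1 without a partner had a median signal of 3.16 and a median width of 218 bp, compared with 4.99 and 548 bp for peaks with a partner. Across 29634 matched peaks, which are not independent replicates, signal ranks had a Spearman rho of 0.879. With both lists restricted to q values of at most 1e-05, the shared fractions were 85.3% for replicate 1 and 85.6% for replicate 2.

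**Figure D1:**
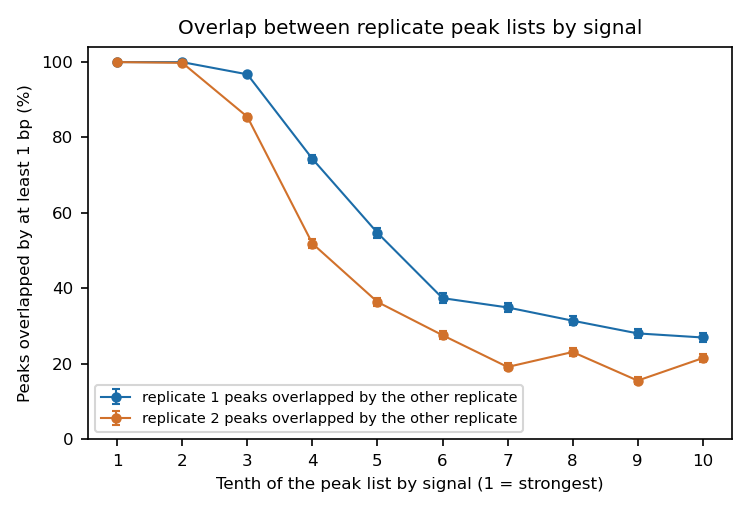
Percentage of peaks overlapped by at least 1 bp by a peak of the other replicate (y axis) in each of 10 equal parts of a replicate's peak list ranked by signal (x axis, 1 is the strongest), with 95% Clopper-Pearson intervals as bars. Sharing is 100% in the strongest part of both lists and 26.9% (replicate 1) and 21.5% (replicate 2) in the weakest.

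The second comparison asked where in the genome the mark lay. Of the replicated peaks, 64.7% (20507 of 31704, 95% Clopper-Pearson interval 64.2% to 65.2%) lay within 1 kb of an annotated transcription start site (TSS), 7.5 times the mean of 8.62% for circularly shifted peaks. A further 5.03% touched an exon, 16.8% lay in introns without touching an exon, and 13.5% lay between genes, where shifted peaks gave 7.18%, 35.4% and 48.8%. Peaks within 1 kb of a TSS had a median signal of 7.62 and a median width of 852 bp, and the 11197 other peaks had 3.52 and 348 bp. In the strongest 10% of the list 98.8% of the peaks were near a TSS, and in the weakest 10% it was 33.9%. The fraction near a TSS was lower in the single-replicate lists, 45.4% for replicate 1 and 40.0% for replicate 2, and rose to 84.0% for replicated peaks with q of at most 1e-05.

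Of 21938 protein-coding genes, 13951 (63.6%) had a replicated peak within 1 kb of a TSS and are called marked here. Any annotated TSS counted, so the promoter peak of a gene can lie far from its 5′ end. Among genes named below, the peaks of Ptch1, Pitx3, Rara, Rarg, Tfap2a, Esrrb and Eef1a1 lay inside the gene, over 5 kb from its 5′ end. The replicate 1 list marked 14391 genes and the replicate 2 list marked 14690. The marked genes with the highest signal included Tnpo1, a nuclear import receptor, at 45.3, and Rbm39 at 45.2 and Srsf6 at 44.7, which encode splicing factors. Marcksl1 at 43.6 and Marcks at 41.3, which encode related substrates of protein kinase C, were also among the 10 highest, with Bicral, Sfpq, Ddx6, Gcat and H1f0. Some of these ranked lower in one library, since Tnpo1 and Marcksl1 fell in the top 0.414% and 1.66% of the replicate 1 list but the top 0.00145% and 0.00291% of the replicate 2 list, and Rbm39 in the top 0.00175% and 0.347%. Gcat and H1f0 shared a single peak with a signal of 39.9 at chromosome 15, 79027415 to 79030754 (mm10), which lay over H1f0 and outside the body of Gcat. The median over all marked genes was 11.2 (quartiles 7.18 and 15.9).

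The third comparison asked which gene lists had marked promoters more or less often than the other protein-coding genes. All 20 neural progenitor genes were marked (adjusted p = 5.6e-04, Fisher's exact test). Among them, Msi1, which encodes an RNA-binding protein of neural stem cells, had a signal of 33.5, Msi2 had 27.7 and Zic1 had 25.9, and the median signal of the list was 16.6. The Msi1 peak at chromosome 5, 115428014 to 115433184, ran over the start of the gene for 3586 bp of the gene body. Sox2, Pax6, Hes5 and Notch1, regulators of the progenitor state, had signals of 23.0, 17.3, 22.3 and 19.8. All 22 pan-neuronal genes were marked as well (adjusted p = 3.1e-04, Fisher's exact test), with the highest signals at Rbfox3 (17.3), Tubb3 (16.9), which encodes a neuronal tubulin, and Dpysl3 (15.6). The Tubb3 peak, at chromosome 8, 123409201 to 123414597, covered 3174 bp of the gene body, and over all annotated genes it held 1783 bp of exons and 3614 bp of introns.

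Of 20 proneural and early differentiation factors, 19 were marked (adjusted p = 4.9e-03, Fisher's exact test). Sox4 and Sox11, transcription factors of newly born neurons, had signals of 37.8 and 34.1, and the Sox4 peak fell in the top 0.0122% of the replicate 1 list and the top 0.312% of the replicate 2 list. The Sox4 peak, at chromosome 13, 28950195 to 28953661, lay wholly within its exon sequence. Ascl1 (9.65), Neurog2 (7.68) and Neurog1 (7.67) lay below the median of marked genes. Atoh1 was the unmarked member, and of the replicate lists only that of replicate 2 had a promoter peak for it, within the top 94.1% of that list. Of 32 transcription factors that define spinal neuron classes, 30 were marked (adjusted p = 5.0e-04, Fisher's exact test), but at a median signal of 4.82. Foxp1 (22.1), Foxp2 (12.9) and Pou4f1 (10.7) were the strongest, the motor neuron factors Mnx1, Isl1 and Lhx3 had 4.04, 4.93 and 4.44, and Vsx2 and Gata3 were unmarked. All 9 neurotransmitter identity genes were marked (adjusted p = 0.0487, Fisher's exact test), led by Slc6a9 at 9.95 and Gad1 at 6.86, and the peak of Gad1 lay at an annotated TSS over 5 kb from the 5′ end of the gene. When genes were stratified by the CpG count of their promoters, the calls ended for the progenitors (adjusted p = 0.087), the proneural factors (adjusted p = 0.104) and the spinal factors (adjusted p = 0.119), all by an exact stratified test. The pan-neuronal call stood in 10 of 10 alternatives. Stratification does not change which genes are marked, and all 20 progenitor genes were. In the upper 2 CpG classes 90.3% to 99.0% of the genes of each autosome were marked. Lists with CpG-rich promoters thus had little room to stand apart, and a call that ended there does not show that CpG content accounts for the marking. At q of at most 1e-05, 62.5% of the spinal factors stayed marked and the call ended (adjusted p = 0.786, exact test). With CpG stratification at that q, a setting chosen after seeing the data, the progenitor genes passed the test (100%, adjusted p = 0.0212), the proneural factors did not (adjusted p = 0.613), and the spinal factors were marked less often than other genes (adjusted p = 8.2e-03, exact stratified test). The neurotransmitter call ended under 5 of 10 alternatives, among them the replicate 2 list alone (adjusted p = 0.0581, Fisher's exact test), in which all 9 genes were still marked.

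Dorsal and ventral patterning genes were next considered, because the neural tube is patterned along this axis. Of 16 dorsal genes, 14 were marked (87.5%, adjusted p = 0.097, Fisher's exact test), including Zic4 (25.9), Zic2 (20.5), Pax3 (17.1) and Pax7 (14.3). Zic4 shared its peak with Zic1. The remaining dorsal genes, Wnt3a and Gdf7, had no promoter peak in the replicated or pooled list. Wnt3a had one in both replicate lists and Gdf7 in the replicate 2 list. Replicated peaks covered 304 bp within 5 kb of the 5′ end of Wnt3a. Of 14 ventral genes, 7 were marked (50%, adjusted p = 0.46, Fisher's exact test). The marked ventral genes were Irx5 (20.8), Irx3 (17.7), Ptch1 (15.7), Nkx6-1 (7.4), Gli1 (4.19), Nkx6-2 (3.82) and Shh (3.26). Foxa2, a floor plate factor, and Nkx2-2, Nkx2-9, Olig1, Olig2, Dbx1 and Dbx2, factors of ventral progenitor domains, had no replicated promoter peak. Of these 7 genes, 5 had a peak in a single-replicate list. Neither the dorsal nor the ventral list passed the test against other genes, and the difference between these lists was not tested. The ventral share was 57.1% in the replicate 1 list and 78.6% in the replicate 2 list, where it lay above that of other genes (odds ratio 1.62, adjusted p = 0.648, Fisher's exact test), as it did at 2.5 kb from a TSS (71.4%, odds ratio 1.27, adjusted p = 0.815, Fisher's exact test). In the replicate 1 list 93.8% and in the replicate 2 list 100% of the dorsal genes were marked, and both lists alone passed the test (adjusted p = 0.0255 and 4.9e-03, Fisher's exact test). The dorsal genes also passed the test at 2.5 kb from a TSS. The dorsal genes did not pass it with CpG stratification (odds ratio 0.912, adjusted p = 0.811, exact stratified test) or at q of at most 1e-05 (75%, adjusted p = 0.269, Fisher's exact test). Stratified by promoter CpG count, the ventral genes were marked less often than other genes (adjusted p = 2.9e-04, exact stratified test), and at q of at most 1e-05 without stratification 28.6% of them stayed marked, also below other genes (adjusted p = 0.0436, Fisher's exact test).

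Of 22 forebrain and midbrain transcription factors, 12 were marked (54.5%, adjusted p = 0.456, Fisher's exact test). Their median signal was 3.53, and the highest values were 5.37 at Pitx3, 4.36 at Hesx1 and 3.82 at Dlx2. The Pitx3 peak, at chromosome 19, 46136111 to 46136664, lay inside the gene, whose 5′ end is at 46148326. The 10 unmarked genes were Foxg1, Otx1, Otx2, Six3, Six6, Rax, Nkx2-1, Tbr1, Fezf1 and Fezf2. In each replicate list 68.2% of the genes were marked, slightly above other genes (odds ratios 1.08 and 1.02, adjusted p = 1.0 for both, Fisher's exact test). With stratification by CpG count the list was marked less often than other genes (adjusted p = 3.9e-03, exact stratified test), and with q of at most 1e-05 only 9.09% of it stayed marked (adjusted p = 9.8e-06, Fisher's exact test). Mature synaptic genes did not pass the test against other genes (12 of 16, adjusted p = 0.479, Fisher's exact test), and Slc17a8, Sst, Tac1 and Calb1 were unmarked. Their odds ratio was 1.59, but 0.882 at q of at most 1e-05 (56.2%, adjusted p = 0.839, Fisher's exact test). Late glial genes did not pass it either (5 of 11, adjusted p = 0.294, Fisher's exact test). The late glial share was 63.6% in the replicate 1 list and 72.7% in the replicate 2 list, where the odds ratio turned from 0.484 to 1.2 (adjusted p = 1.0, Fisher's exact test). Mbp (13.7) and Slc1a2 (12.8) were marked, whereas Mog, Mag and Mobp, which encode myelin proteins, were not. The Mbp peak lay at the outermost annotated 5′ end of the gene (chromosome 18, 82475146), and the gene runs to 82585637. Promoters of its other transcripts were not examined separately, so this peak does not show marking at a myelin transcript. In the retinoic acid pathway 8 of 10 genes were marked (adjusted p = 0.431, Fisher's exact test), led by the receptors Rara (13.5) and Rarg (8.14), and Cyp26a1 and Rbp1 were not. Rbp1 nevertheless had 3566 bp covered by replicated peaks within 5 kb of its 5′ end, beyond the 1 kb set for a promoter, and Cyp26a1 had 0 bp. With the 5′ end alone 60% of the retinoic acid list was marked, and the odds ratio turned from 1.95 to 0.972 (adjusted p = 1.0, Fisher's exact test).

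Lists of other lineages were compared in the same way. Of 15 neural crest genes, 13 were marked (adjusted p = 0.144, Fisher's exact test), with Tfap2a at 15.3, Twist1 at 9.72 and Sox10 at 4.89, and Plp1 and Phox2b unmarked. At q of at most 1e-05 the same fraction, 86.7%, passed the test (adjusted p = 0.0474, Fisher's exact test). Of 18 somite and muscle genes, 13 were marked (adjusted p = 0.651, Fisher's exact test), with Col2a1 at 17.7 and Foxc1 at 12.2, but Myf5, Myf6 and Myog were not; at q of at most 1e-05 the fraction was 33.3% and below that of other genes (adjusted p = 0.0466, Fisher's exact test). Of 15 endothelial genes, 10 were marked (adjusted p = 1.0, Fisher's exact test), led by Fli1 at 13.9, while Pecam1, Cdh5 and Tek were not. The endothelial odds ratio of 1.09 turned to 0.594 with the 5′ end alone (46.7%, adjusted p = 0.403) and to 0.364 at q of at most 1e-05 (33.3%, adjusted p = 0.0831, Fisher's exact test).

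The remaining lineage lists were marked less often than other genes. Of 14 cardiac genes, 1 was marked, Gata5 at 4.29 (adjusted p = 1.1e-04, Fisher's exact test). Of 16 blood and macrophage genes, 4 were marked (adjusted p = 5.8e-03, exact test), namely Klf1 (5.70), Gypa (5.64), Hba-x (3.67) and Epor (3.06), and the globin genes Hbb-bh1, Hbb-y, Hba-a1 and Hba-a2 were not. Of 15 liver and endoderm genes, 4 were marked (adjusted p = 9.2e-03, exact test). Among these, the peak at Foxa3 (16.1) lay outside the body of Foxa3, over another annotated gene, and Trf (5.98), Epcam (4.44) and Cdh1 (3.52) followed, whereas Alb, Afp and Ttr had no peak. Of 13 pluripotency and germ line genes, 3 were marked (adjusted p = 0.0105, exact test), namely Klf4 (8.41), Dazl (5.04) and Esrrb (3.52), and Nanog and Pou5f1 were not. Of 11 epidermal genes, 2 were marked (adjusted p = 5.8e-03, exact test), Krt10 (11.8) and Krt1 (9.81), with Krt5 and Krt14 unmarked. The peaks of Krt10 and Krt1 lay inside the gene, over 2 kb from its 5′ end but near another annotated TSS, and with the 5′ end alone 0% of the epidermal genes were marked. In replicate 2 alone 50% of the cardiac genes had a promoter peak, compared with 28.6% in replicate 1, and the cardiac call ended on that list (adjusted p = 0.333, Fisher's exact test), as did the pluripotency call (adjusted p = 0.0598, Fisher's exact test). With CpG stratification the calls for blood (adjusted p = 0.811) and epidermis (adjusted p = 1.0) ended by the exact stratified test, and the direction against other genes turned for blood.

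Lists of broadly used genes were marked nearly in full. All 20 cell cycle genes (adjusted p = 5.6e-04), all 14 housekeeping genes (adjusted p = 6.5e-03) and 80 of 81 genes of the cytosolic ribosomal protein list (adjusted p = 8.5e-14) were marked by Fisher's exact test. The highest of each were Ccna2 at 18.3, Eef1a1 at 35.3 and Rps6 at 32.3. The ribosomal list was drawn by symbol, so it also held genes with related symbols, such as Rps19bp1 and Rpl7l1, which were marked. Rps27rt was the gene of that list without a promoter peak, although replicated peaks covered 1292 bp within 5 kb of its 5′ end. Of the chemosensory receptor genes, 1 of 1135 olfactory receptors, Olfr94, and 1 of 329 vomeronasal receptors, Vmn1r4, were marked, 0.0881% and 0.304% (adjusted p = 4.0e-143 for the vomeronasal list, Fisher's exact test). The Olfr94 peak had a signal of 3.07 and lay wholly in coding sequence. Of the 1265 bp of the Vmn1r4 peak, 594 bp lay in the body of Vmn1r4 and 82 bp outside annotated genes. The rest lay over another annotated gene. The cell cycle call (adjusted p = 0.811) and the housekeeping call (adjusted p = 0.111) ended with CpG stratification, in an exact test, and the ribosomal and both receptor calls did not. The cell cycle and housekeeping lists were marked in full, so the stratified test had little room to call them. When q of at most 1e-05 was added to the stratification, after seeing the data, the housekeeping genes passed the test (adjusted p = 0.0289) and the cell cycle genes did not (adjusted p = 0.225, exact stratified test).

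**Figure D2:**
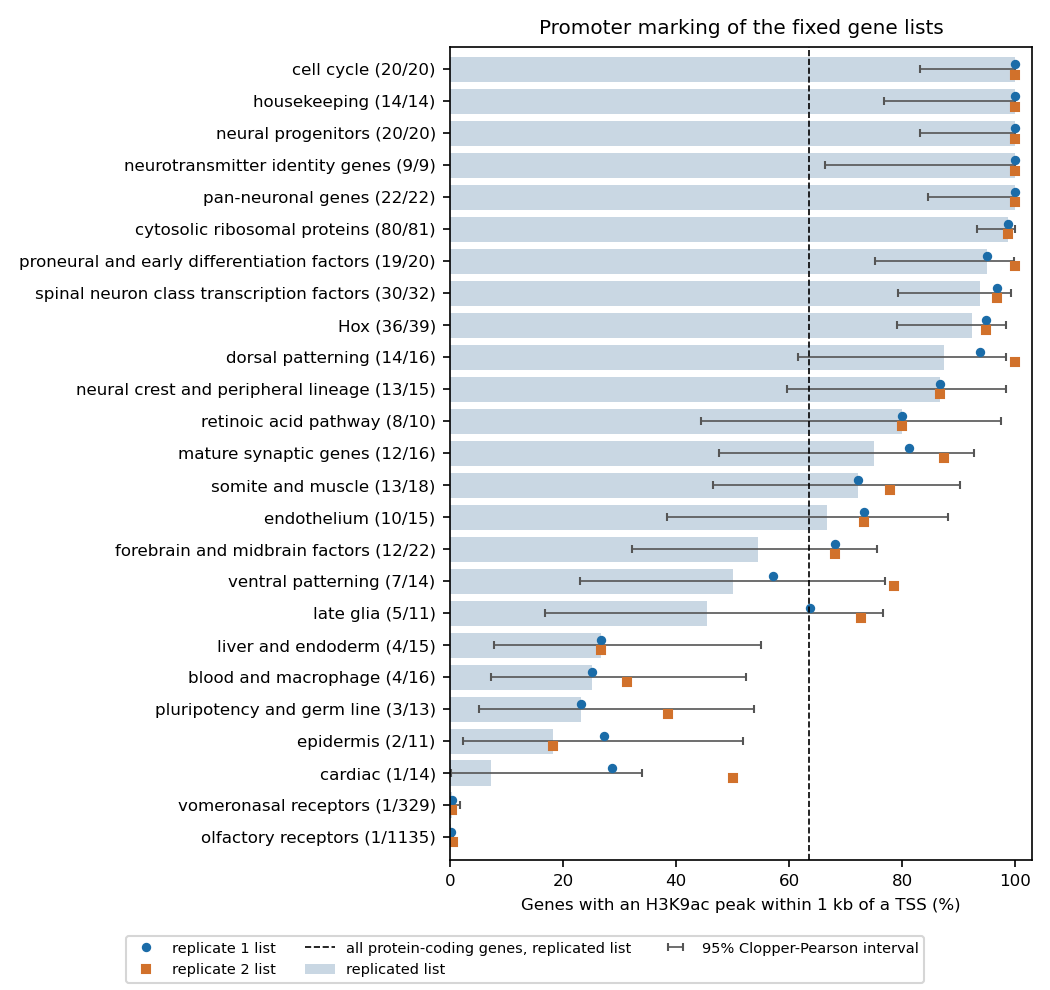
Percentage of the genes of each fixed list with an H3K9ac peak within 1 kb of a TSS (x axis), with the marked and total genes of the list in parentheses (y axis). Bars show the replicated list with 95% Clopper-Pearson intervals, circles replicate 1, squares replicate 2 and the dashed line all protein-coding genes (63.6%), with progenitor, pan-neuronal and cell cycle genes at 100% and cardiac genes at 7.14%.

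The fourth comparison asked how broadly the mark spread around marked genes. The median length covered by replicated peaks within 5 kb of the gene's 5′ end was 1455 bp over 13951 marked genes (quartiles 942.5 and 2084.5 bp). Hox genes were the broadest list, with a median of 9279.5 bp, followed by neural progenitor genes with 4339.5 bp and proneural factors with 3343 bp (adjusted p = 8.4e-05 for each, permutation test, from the smallest unadjusted p of 2.0e-05). The 36 marked Hox genes lie in 4 clusters, and the 5′ ends of 7 lie in 1 peak. Neighbouring Hox genes thus count the same peaks, which the random sets do not reproduce, so the Hox p is too small. Within the progenitor list Zic1 had 9201 bp covered, Dll1 7242 bp, Sox2 6810 bp and Msi1 6428 bp. Housekeeping genes (2628 bp, adjusted p = 1.4e-03), dorsal patterning genes (2395.5 bp, adjusted p = 8.0e-03), pan-neuronal genes (2122 bp, adjusted p = 0.0153) and ribosomal protein genes (2078.5 bp, adjusted p = 8.4e-05) were also broader by the permutation test. Covered length takes in every replicated peak of the window, also those at neighbouring genes, and the random sets were not matched on gene spacing. A broader list can therefore hold genes with close neighbours. Forebrain and midbrain factors were narrower, with a median of 391.5 bp (adjusted p = 8.4e-05, permutation test), as were mature synaptic genes with 782.5 bp (adjusted p = 0.0266, permutation test) and the 4 marked blood genes with 482 bp (adjusted p = 0.0282, permutation test). The other 11 lists with at least 3 marked genes did not pass the test, among them spinal neuron factors (1630.5 bp, adjusted p = 0.401), cell cycle genes (1956.5 bp, adjusted p = 0.0698), neurotransmitter identity genes (2156 bp, adjusted p = 0.107) and ventral genes (2077 bp, adjusted p = 0.177) by the permutation test. Medians in the replicate lists for the progenitors were 4433.5 bp in replicate 1 and 4332 bp in replicate 2. In the replicate 2 list alone the spinal factors (1988 bp, adjusted p = 0.0474) and cell cycle genes (2200 bp, adjusted p = 0.0196) were broader and the pluripotency genes narrower (541 bp, adjusted p = 0.0434, permutation test). In the replicate 1 list alone the ventral genes were broader (2463 bp, adjusted p = 0.0469), the endothelial genes narrower (783 bp, adjusted p = 0.0394), and the call for blood genes ended (769 bp, adjusted p = 0.157, permutation test). Matching on promoter CpG content ended the calls for synaptic genes (adjusted p = 0.137, permutation test) and for blood genes, and a 2.5 kb window ended those for dorsal (adjusted p = 0.168), housekeeping (adjusted p = 0.380) and blood genes (482 bp, adjusted p = 0.0568, permutation test). The 2.5 kb window also brought a call for endothelial genes, which were then narrower (660.5 bp, adjusted p = 0.0253, permutation test). A 10 kb window ended the pan-neuronal call (adjusted p = 0.0660) and brought one for ventral genes, which were then broader (4336 bp, adjusted p = 1.0e-03, permutation test). The blood genes turned direction in that window and were no longer narrower.

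**Figure D3:**
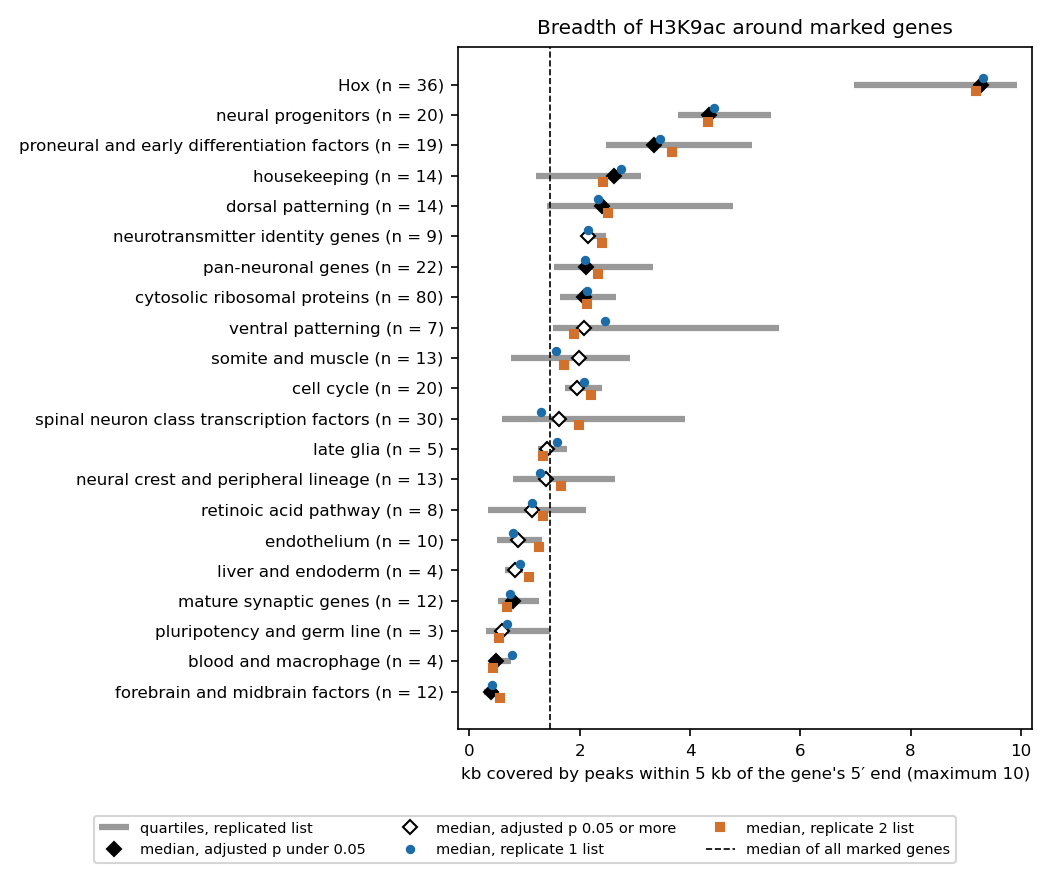
Length in kb covered by peaks within 5 kb of the gene's 5′ end (x axis, at most 10) for the marked genes of each list (y axis, n in parentheses). Diamonds are medians in the replicated list (filled where the adjusted p of the permutation test is under 0.05), grey bars its quartiles, circles and squares medians in the replicate 1 and replicate 2 lists, and the dashed line the median of 1455 bp over all marked genes, with Hox genes at 9279.5 bp and forebrain and midbrain factors at 391.5 bp.

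The Hox genes, which set position along the body axis, were examined cluster by cluster. Replicated peaks covered 82.1% of the Hoxa cluster, 55.9% of Hoxb, 70.9% of Hoxc and 61.7% of Hoxd, which was 84.6, 57.6, 73.1 and 63.6 times the coverage of the genome. The Hoxb interval was the longest, at 173.9 kb, because it begins at Hoxb13 (96194316). The next gene, Hoxb9, starts at 96271457, and the first replicated peak of the interval starts at 96250814. The low Hoxb share depends on this stretch, so the shares do not rank the clusters. The replicates gave 82.7% and 82.1% for Hoxa, 55.7% and 56.4% for Hoxb, 69.2% and 73.8% for Hoxc, and 62.6% and 62.9% for Hoxd in replicates 1 and 2. A single peak of 73.05 kb, the widest of the replicated list, spanned chromosome 11, 96268146 to 96341195 (mm10), and held the 5′ ends of 7 genes, Hoxb3 to Hoxb9. Of its length, 15763 bp lay in exons of any annotated gene, 33566 bp in introns and 23721 bp outside annotated genes. The corresponding widest Hoxb peak measured 76.2 kb in replicate 1 and 62.0 kb in replicate 2. The next widest peaks of the list lay at Hoxc9 (15.4 kb, chromosome 15, 102970047 to 102985487) and Hoxa7 (14.7 kb, chromosome 6, 52213549 to 52228241). The widest Hoxc peak measured 19.6 kb in replicate 1 and 15.4 kb in replicate 2, and the widest Hoxa peak 29.0 and 14.7 kb. Of the 15 protein-coding genes with the greatest covered length, 13 were Hox genes, and the others, Gm28308 and Gm28230, are annotated within the Hoxa and Hoxd clusters.

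Of the 39 Hox genes, 36 were marked (92.3%, adjusted p = 3.1e-04, Fisher's exact test), with the highest signals at Hoxb2 (39.1) and at Hoxd3 and Hoxd4, which shared a peak (37.9). All 12 genes of paralogue groups 1 to 4, all 11 of groups 5 to 8 and all 7 of groups 9 and 10 were marked, with median covered lengths of 9250, 9914 and 9149 bp. These lengths were taken at the outermost annotated 5′ end of a gene, which can lie at another paralogue. Hoxc5 starts within Hoxc10 (at 102967443), and Hoxa3 starts beside Hoxa7 (at 52213336) and shares its peak. Hoxd3 and Hoxd4 start at 74711927 and 74711929. The values by group therefore partly describe promoters of other paralogues. In groups 11 to 13, which are the posterior paralogues, 6 of 9 were marked, and the marked genes had a median covered length of 2634 bp (2148.5 bp for the same genes in replicate 1 and 3395.5 bp in replicate 2). Within them Hoxa11, Hoxc11 and Hoxd11 had 5583, 4936 and 4009 bp, whereas Hoxc12, Hoxd13 and Hoxc13 had 1259, 496 and 481 bp. Among the anterior genes, Hoxb1 and Hoxd1 had 1767 and 1397 bp. These groups were described and not tested against each other. Hoxa13, Hoxb13 and Hoxd12 had no replicated promoter peak, although Hoxa13 had a peak in the replicate 1 list and Hoxd12 one in the replicate 2 list. The Hox promoter call ended with CpG stratification (adjusted p = 0.280, exact stratified test), whereas the breadth call stood in 6 of 6 alternatives.

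**Figure D4:**
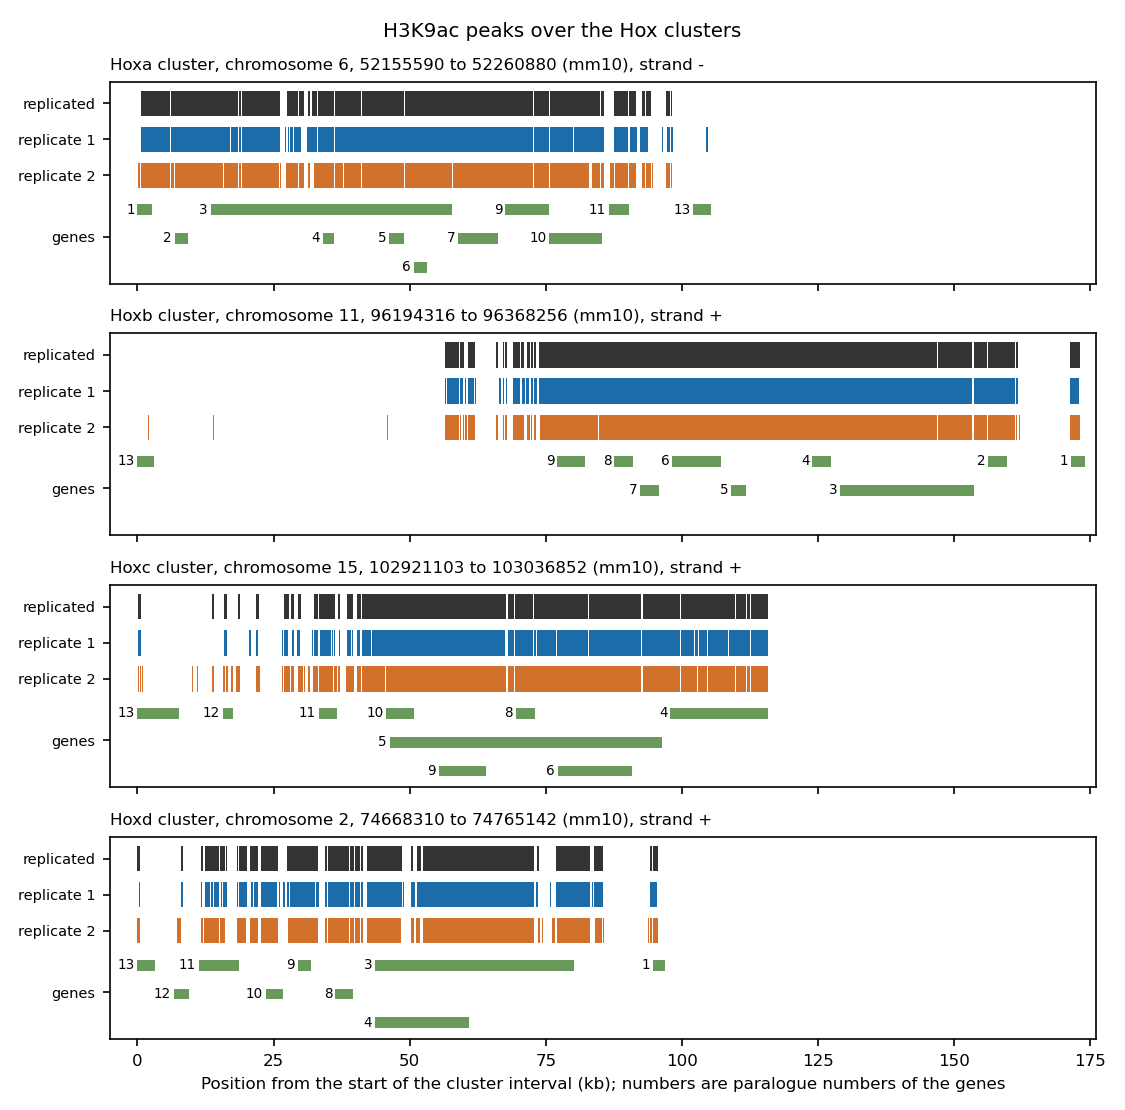
Maps of the 4 Hox clusters (mm10), with position from the start of each cluster interval in kb on the x axis. Bars in black, blue and orange are peaks of the replicated, replicate 1 and replicate 2 lists, and green bars are annotated genes with their paralogue numbers; covered length within 5 kb of the 5′ end is low at group 13 (0 to 496 bp) and Hoxd12 (269 bp), and also at Hoxc12 (1259 bp), Hoxb1 (1767 bp) and Hoxd1 (1397 bp).

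The last comparison asked whether either replicate marked more genes than the other when the 57218 strongest peaks of each were taken. Both marked 13993 genes, replicate 1 alone marked 398 and replicate 2 alone marked 503 (p = 5.2e-04, exact McNemar test, two-sided). With all peaks of each list, replicate 1 alone marked 306 and replicate 2 alone marked 605 (p = 2.2e-23, exact McNemar test). The test compares these 2 libraries. It sets the genes marked in replicate 1 alone against those in replicate 2 alone, and does not measure how far the same genes were marked. None of the 25 gene lists passed the exact McNemar test between the replicates, with 0 lists under an adjusted p of 0.05 and 0 under an unadjusted p of 0.05. Only 1 list, the cardiac one, had enough genes in a single replicate for an unadjusted p under 0.05 to be possible, so this test says little about the lists. The lists with most genes in 1 replicate alone were cardiac (2 in replicate 1 alone and 4 in replicate 2 alone), ventral patterning (1 and 4) and olfactory receptors (1 and 4, adjusted p = 1.0 for each, exact test). In the full lists, the strongest promoter peaks in replicate 1 at genes with none in replicate 2 were at AC140267.1, Ptger1, Dnmt3l, Gstm6 and Ermard, and those in replicate 2 and not in replicate 1 were at Egr3, Slc35g3, Ushbp1, Gabra3 and Trim14. The strongest ranked in the top 11.3% of the replicate 1 list (AC140267.1) and the top 12.9% of the replicate 2 list (Egr3). Of the 10 genes, 6 (Ptger1, Ermard, Egr3, Slc35g3, Gabra3 and Trim14) nevertheless had a promoter peak in the replicated list.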

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

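The replicated list held 5 peaks on contigs outside the assembled chromosomes, which no comparison used, and they are named here because they are signal outside the regions compared. They lay on 3 contigs, and their signals were 15.02, 4.60, 4.44, 3.34 and 1.63. No explanation was tested for them.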

How the results depend on the processing

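The combination of CpG stratification with q of at most 1e-05, and the use of 10 neural lists for distal peaks, were chosen only after the data were seen. The cause of the changes was not tested, except where fewer or weaker peaks follow from the setting itself. Reciprocal overlap of at least 50% moved the shared fractions to 41.4% (replicate 1) and 34.4% (replicate 2) and rho to 0.908. With q of at most 1e-05 the shared fractions were 85.3% and 85.6%, rho 0.892 and the share near a TSS 84.0%. The −log10 p column gave a rho of 0.894. The share near a TSS was 59.8% at 500 bp, 72.6% at 2.5 kb, 59.1% in the pooled list, 60.1% with protein-coding genes alone, and 40.0% to 45.4% with a replicate left out. Lists marked more often than other genes numbered 9, but 3 with CpG stratification and 5 when q of at most 1e-05 was added, and 9 to 10 with a replicate left out; those marked less often numbered 7, but 10 at q of at most 1e-05, 9 with stratification added, and 5 to 7 with a replicate left out. Lists with narrower marking numbered 3, but 5 in the pooled list, 1 when matched on CpG and 4 to 6 with a replicate left out, and broader lists numbered 7 (8 to 9). Coverage in the pooled list was 82.9% of Hoxa and 62.4% of Hoxd, and with a replicate left out it was 82.1% to 82.7% for Hoxa, 55.7% to 56.4% for Hoxb, 69.2% to 73.8% for Hoxc and 62.6% to 62.9% for Hoxd. Marking turned direction against other genes for these lists. At q of at most 1e-05 these were somite and muscle (33.3%), endothelial (33.3%) and synaptic genes (56.2%), and all 3 with stratification added. Stratification alone turned blood (25%) and dorsal genes (87.5%), and both settings together turned dorsal genes (75%), spinal neuron factors (62.5%, below other genes at adjusted p = 8.2e-03, exact test), epidermis (18.2%), late glia (45.5%) and retinoic acid genes (60%). The 5′ end alone turned endothelial (46.7%) and retinoic acid genes (60%), 500 bp (60%) and a background without receptors (66.7%) endothelial genes, and 2.5 kb ventral genes (71.4%). With a replicate left out the shares were 57.1% to 78.6% for ventral and 63.6% to 72.7% for late glial genes, turned without replicate 1, and with either left out those of forebrain and midbrain factors turned (68.2% in both). Breadth turned in the 2.5 kb window for spinal factors (1221 bp), late glia (1415 bp), neural crest (1389 bp) and somite genes (917 bp), and in the 10 kb window for retinoic acid (1828.5 bp), neural crest (1604 bp) and blood genes (1860.5 bp). It turned in the pooled list for neural crest (1584 bp) and when matched on CpG for late glia (1415 bp) and neural crest (1389 bp). With a replicate left out it turned without replicate 1 for neural crest (1272 to 1655 bp), and without replicate 2 for spinal factors (1289 to 1988 bp) and late glia (1335.5 to 1587 bp). For single lists and distal peaks 296 of the alternatives kept direction and side of the threshold, 35 turned direction as above, and with direction kept 26 ended a call and 20 brought one. No paired analysis was possible because there is 1 group. Depth is unknown, so an unmarked promoter was not detected at this depth and is not shown to lack the mark.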

Other observations

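The test of the difference in excess distal peaks between the neural and the other-lineage lists, and the tests on 10 neural lists, were chosen only after the results were seen, and the regions and genes of the first paragraph were chosen after their values were seen. Each other test had its prediction written before its result, although the lower signal of X-linked genes without matching had been seen when the matched comparison was run. The fourth widest replicated peak, 13.2 kb at chromosome 7, 79499056 to 79512254 (mm10), held no protein-coding gene and lay over A330074H02Rik and over Mir9-3hg and Mir9-3, the host transcript and the gene of a microRNA known from neural development. The other 9 of the 10 widest peaks lay in Hox clusters. Distal peaks, over 2.5 kb from any annotated TSS, numbered 8677 with a median signal of 3.52. Assigned to the nearest protein-coding 5′ end, they were most numerous at Gse1 with 44, Zfp36l1 with 29 and Zfp608 with 25. Among list genes Notch1 had 17, Sox4 and Sox9 had 16 each, Lhx5 and Msi2 had 15 each, and Pax7 and the ribosomal protein gene Rps24 had 14 each.

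Marked genes of 6 neural lists (progenitors, proneural, pan-neuronal, ventral, dorsal and spinal neuron factors, a choice not part of the written prediction) had a mean of 3.04 distal peaks (n = 112), compared with 0.532 for random marked genes (p = 2.0e-04, permutation test, the smallest value 10000 resamples can give). Progenitor genes had 4.80 ± 5.29 (SD, n = 20) and proneural factors 4.47 ± 4.48 (SD, n = 19), whereas pan-neuronal genes had 1.00 ± 1.45 (SD, n = 22), and of the neural lists left out neurotransmitter genes had a mean of 0.667, late glial genes 0.600, forebrain and midbrain factors 0.500 and synaptic genes 0.0833. Wider flanks argue poorly for the excess, since random marked genes matched on flank length had a mean of 0.865 and 95% of random lists lay between 0.536 and 1.29, below the 3.04 observed and, for all 10 neural lists, at most 1.18 against 2.37 (n = 150). Fragments of broad promoter domains do so as well, since peaks over 10 kb from any TSS still averaged 1.43, while 95% of random lists lay between 0.125 and 0.500, or up to 0.830 when matched on flank length. Marked genes of 7 other-lineage lists (somite and muscle, endothelium, blood and macrophage, liver and endoderm, cardiac, pluripotency and germ line, epidermis) had 1.03 (n = 37), within the matched range of 0.243 to 1.32. The excess over flank-matched genes was 1.81 peaks higher in the 6 neural lists (p = 1.4e-03, permutation test) and 1.17 higher in all 10 (p = 0.0285, permutation test). Neural crest genes (mean 1.23, n = 13) and retinoic acid genes (mean 1.88, n = 8) were in neither group. This difference was found and tested on the same lists, and promoter signal was not matched. With no second tissue, whether the excess is a feature of the neural tube could not be tested.

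X-linked promoters were marked less often and at lower signal. Of 948 X-linked genes 45.4% were marked, compared with 65.0% of 20807 autosomal genes (p = 2.7e-33, Fisher's exact test), and the median signal was 6.76 against 11.4, a ratio of 0.595 (0.599 in replicate 1 and 0.623 in replicate 2). CpG content argues poorly for the signal difference, since within 5 classes of CpG count the ratio was 0.678, and the 19 autosomes ranged from 0.942 to 1.08. For the share marked, gene families on X that cannot be marked or mapped remain open. In the upper 2 classes 93.1% of X-linked genes were marked, within the autosomal range of 90.3% to 99.0%. These classes held 188 of the 948 X-linked genes, and shares there had little room to differ between chromosomes. The comparison does not separate such families from CpG content. Fewer active copies of X than of autosomes per cell in pools of both sexes predicted a matched ratio below 0.9 and below every autosome, and the ratio of 0.678 met this. The prediction largely restates the lower X signal already seen, and any cause acting on the whole X would meet it. It therefore cannot decide for this cause, which remains open. Mappability was not examined and other causes are untested.

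A promoter peak in a replicate list but none in the replicated list was found for 1045 genes, 201 of them in both replicate lists, including 8 of the 13 unmarked cardiac genes and 5 of the 7 unmarked ventral genes. Calls in both lists were 2.53 times the 79.6 expected for independent calls within CpG classes (at most 94 in the central 95% of simulations). Independent chance calls in the replicates predicted fewer, but this does not decide against them. Only CpG class was matched, and genes also differ in their number of annotated TSS. The genes compared included 1134 unreplicated olfactory receptors, of which 5 had a call in a replicate list. Such differences raise calls in both lists even where calls are independent. Calls near the detection threshold remain open, because the median −log10 q of the 1045 genes was 2.43, compared with 35.5 for genes of the replicated list. Of the 1045 genes, 40 reached 5. A different call or filter of the pooled list, which held fewer peaks than either replicate list, remains open as well. Background at CpG-rich promoters remains open too, because the median CpG count of the 1045 genes was 2.25 times that of genes with no peak in any list. At 18 it was nevertheless below the 61 of replicated genes. Weak marking in a small share of the cells could give the same values, and no biological explanation was tested.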
